A study of Oryza sativa with 9 samples.

How the data were processed

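Spikelet polyA RNA of 9 samples, 3 for each of the genotypes f5-i/i, f5-i/j and f5-j/j, was fragmented, reverse transcribed with random primers and sequenced on an Illumina HiSeq 2000, per the labels' protocols. Nothing in the labels says whether the 3 samples of a genotype came from separate plants. BWA, Bowtie and RSEM are named in the submitters' processing notes, without version, role or order. The genome build, the annotation version, the normalization and the program that gave the probabilities are not given in the sources used here, and neither is the read depth of any sample.

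The deposited tables analysed were 3 filtered lists, 1 for each pair of genotypes, and the full set of tested transcripts was not analysed here. Each row is a transcript with a rice locus identifier, 2 genotype means, a ratio, a probability, a coding length (100% of the values are multiples of 3) and annotation text. The deposited means are signal values averaged by the authors over the samples of a genotype, per the file headers; their unit is not stated, and 0.01 is the lowest value and was read as standing for no detection. The genotype of each column was taken from the table names and from means that recur between tables: for transcripts in 2 tables the means of a genotype differed by 0. The deposited log2 ratio is the log2 of the ratio of these 2 means, which was checked by recomputing it. The deposited probability is a score between 0.8 and 1, per the file headers a probability of differential expression and not a p-value. Among pairs of transcripts where 1 had both the larger ratio and the larger difference of means, over 99.9% also had the larger probability in each of the authors' deposited tables (99.95%, 99.96% and 99.96%), so the score holds little about the spread between replicates of each transcript. Counts of reads cannot be recovered from such means, and no model of single samples was fitted.

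Transcripts were counted as the authors' deposited tables give them. For tests of groups and chromosomes the unit was the locus, and loci with transcripts going both ways (12, 8 and 8 in the tables f5-i/j against f5-i/i, f5-i/j against f5-j/j and f5-i/i against f5-j/j) were left out of tests of direction. Several transcripts of a locus can carry identical values, so the listed transcripts are fewer independent measurements than their number. The division of reads between transcripts of a locus, or between near-identical genes such as those of the light-harvesting and heat shock families, is an estimate of the authors' counting and makes single transcripts uncertain. Folds are ratios of the authors' means and are not given where a mean is 0.01.

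The 20 gene groups, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The groups were ER protein folding, heat shock and chaperones, photosynthesis (for the green hull tissue in a spikelet), sugar and starch, chromatin with cell cycle and cytoskeleton, hormone, lipid and cuticle, phenylpropanoid and flavonoid, cell wall and pollen tube, transport, proteases and cell death, oxidation and detoxification, mitochondrial respiration, ubiquitin and F-box, defence and receptor kinases, MADS with MYB and bHLH transcription factors, WRKY with NAC, ERF and bZIP transcription factors, transposon, meiosis, and tapetum and pollen wall. Members were found by words in the deposited descriptions, those of the meiosis group also by locus identifier, and those of the tapetum and pollen wall group by locus identifier alone. Only 24 of 25 tapetum and 6 of 15 meiosis loci had an identifier of the kind the tables use. Words also matched a flavonoid enzyme as ubiquitin and F-box and a MATE transporter as defence, and the groups were kept as fixed. Descriptions were present for 66.7%, 76.9% and 69.6% of the transcripts in the 3 tables. Direction was tested by a two-sided Fisher's exact test of higher against lower loci, group members against the other listed loci, with Benjamini-Hochberg adjustment over the 46 tests that had a member. Over-representation was tested by a one-sided Fisher's exact test against all loci of the 3 tables, for groups with at least 5 loci, over 27 tests. The plan had named all annotated genes as the background of that test and of the chromosome test. The reference table used here (assembly ASM3414082v1) carries other locus identifiers and no descriptions. The union of the 3 tables therefore served as background in place of the annotated genes. For the same reason windows of chromosome length were not counted, and stretches of 2000 locus numbers were used in their place. Overlap of the tables was not tested against annotated genes either, since the number of transcripts tested is not given in the sources used here. The share moving the same way was simulated for 400000 transcripts without effect, with thresholds set to give the observed overlap rather than the share called. Simulated values were normal, of equal variance in the 3 genotypes, and had no lowest value. Loci per chromosome were tested for 12 chromosomes and 3 tables with adjustment over the 36 tests.

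Named transcripts followed the rule: in each table the 8 with the largest ratio in each direction among those with a higher mean of at least 5; listed members of the tapetum and meiosis lists, at most 12; the 6 in each direction apart from both homozygotes with the largest smaller ratio; the 4 with the largest ratio of a group passing a test; and at most 8 in the densest stretch of chromosome 5. The text names part of them. After the tables were seen, the rule was also applied with transcripts at the lowest value left out. Transcripts without a description were to be named at most 2 each way. Chosen after their values were seen were HSP70, HSP20 and DnaJ A2 as abundant chaperones, and the HtpG transcript LOC_Os08g39140.3. So were the light-harvesting complex II transcripts LOC_Os09g17740.1 and LOC_Os03g39610.2, and LOC_Os06g51260.1, described as LHY. The same holds for the endopeptidases described as KDEL-tailed, and for peroxidases LOC_Os12g02080.2, LOC_Os03g22010.1 and LOC_Os05g04500.1. Granule-bound starch synthase, beta-amylase, the jasmonate ZIM-domain protein and the transcripts that open the other observations were also chosen so.

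The direction test was tested on simulated data for f5-i/j against f5-i/i, with the directions of all loci drawn at random and its 14 heat shock loci set lower with a probability of 95%. The planted group was recovered in 64% of 50 runs, and 0.0444% of the other tests were called. Directions were drawn independently for each locus. Loci of a group may move together in the data, and the tests take them as independent. The share called in the simulation thus does not measure false calls in the data. Alternatives were an absolute log2 ratio of at least 2, a probability of at least 0.9, a higher mean of at least 1 or 5, transcripts at the lowest value left out, loci of chromosome 5 left out, directions apart, and a margin of 1.5-fold for the position of the heterozygote. Computation used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.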

Results

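The data covered spikelets, the floral units of rice (Oryza sativa), from BC14F2 plants, which descend from repeated backcrossing followed by selfing. The plants segregated at f5, a locus of hybrid male sterility between rice subspecies, and carried the genotype f5-i/i, f5-j/j or f5-i/j. PolyA RNA of 9 samples was sequenced, 3 for each of the 3 genotypes. The question was which transcripts and pathways differ between the heterozygote and the homozygotes. The values analysed were the authors' mean abundance of each genotype, in a unit not given in the sources used here, for transcripts in the authors' deposited tables of differential expression. No values of single samples were analysed here, so no mean below has an error, read depth is unknown, and differences could not be set against the spread between replicates. Every transcript had a probability of differential expression of at least 0.8 in the authors' deposited table, and p-values below concern gene groups or chromosomes within these tables. The lowest mean was 0.01, and no fold is given against it. A mean just above 0.01 may still include samples at the lowest value, so very large folds are uncertain. Gene descriptions are those of the files, most of them taken over from similar proteins of other organisms.

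For f5-i/j against f5-i/i the authors' deposited table held 480 transcripts of 427 loci, 256 of them higher and 224 lower in the heterozygote. For f5-i/j against f5-j/j the authors' deposited table held 350 transcripts of 313 loci, 156 higher and 194 lower. The homozygotes differed in 421 transcripts of 379 loci in the authors' deposited table, 190 higher and 231 lower in f5-i/i than in f5-j/j. Many of these transcripts stood at the lowest value in 1 of the 2 genotypes compared, namely 228, 203 and 214 of the transcripts in the 3 authors' deposited tables. Without them the split was 140 higher and 112 lower for f5-i/j against f5-i/i, 51 and 96 for f5-i/j against f5-j/j, and 89 and 118 for f5-i/i against f5-j/j. The median fold among the transcripts above the lowest value was 7.12, 6.53 and 7.37 in the same order.

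**Figure D1:**
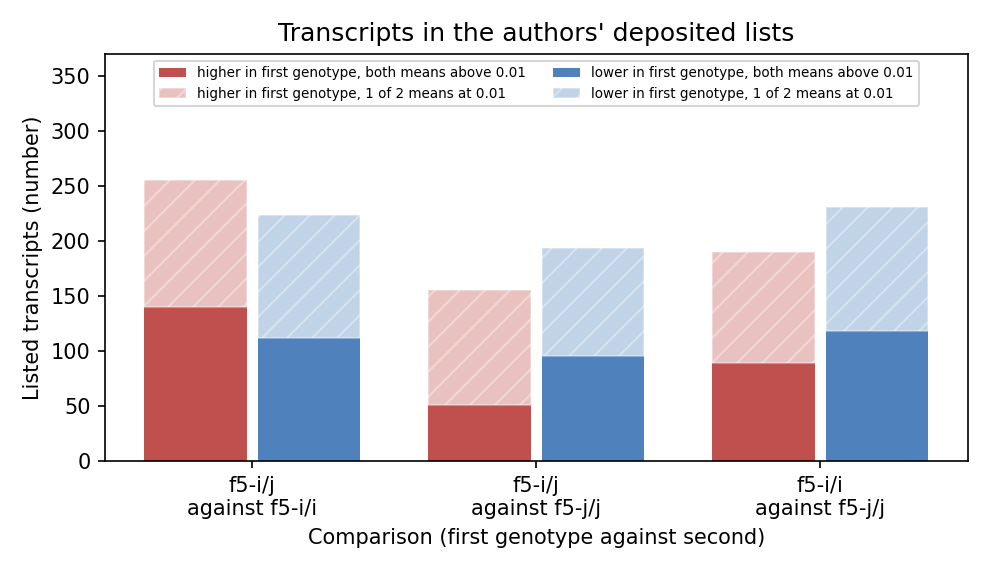
Number of transcripts (y axis) in each of the 3 authors' deposited tables (x axis), higher (red) or lower (blue) in the first genotype named; solid parts have both means above 0.01 and hatched parts have a mean of 0.01 in 1 of the 2 genotypes, the second for red and the first for blue. The solid parts hold 140 and 112, 51 and 96, and 89 and 118 transcripts.

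Against f5-i/i, the heterozygote had higher transcript levels of photosynthesis loci and lower levels of heat shock and chaperone loci. All 20 photosynthesis loci with a single direction in the authors' deposited table were higher in f5-i/j and 1 further locus had transcripts going both ways, while 48.1% of the other listed loci were lower (two-sided Fisher's exact test, adjusted p = 0.000264). The 22 higher transcripts above the lowest value differed by a median of 4.24-fold and by up to 39.8-fold. Protochlorophyllide reductase (LOC_Os04g58200.1), which acts in chlorophyll synthesis, had the authors' mean of 354 in f5-i/j and 31.1 in f5-i/i. Light-harvesting complex proteins bind the chlorophyll of the photosystems. The authors' mean was 90.4 against 2.27 for light-harvesting complex I protein 2 (LOC_Os07g38960.2) and 171 against 15.9 for light-harvesting complex II protein 2 (LOC_Os03g39610.1). Chlorophyllide a oxygenase (LOC_Os10g41780.1) and the photosystem II 10 kDa protein (LOC_Os08g10020.3) were at 23.1 and 9.80 in f5-i/j and at the lowest value in f5-i/i by the authors' mean. Photosystem I subunit XI went both ways, with the authors' mean of 115 against 24.0 for LOC_Os12g23200.1 and 1.12 against 15.9 for LOC_Os12g23200.2. Photosynthesis loci were also over-represented in this authors' deposited table, which held 21 of the 22 such loci found in any of the 3 (95.5%, against 57.6% of other loci; one-sided Fisher's exact test, adjusted p = 0.00305). By description, 2 listed loci were of LHY, a MYB-related transcription factor of the circadian clock. LOC_Os08g06110.2 had the authors' mean of 43.1 in f5-i/j and 1.45 in f5-i/i. LOC_Os06g51260.1 had 13.6 and 14.1 and was not listed for this comparison.

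All 14 heat shock and chaperone loci with a single direction in the authors' deposited table were lower in f5-i/j than in f5-i/i, and 1 locus went both ways, while 43.9% of the other loci were lower (two-sided Fisher's exact test, adjusted p = 0.000312). Over-representation of the group did not pass here, with 15 of 19 loci (78.9%, against 58.2% of other loci; one-sided Fisher's exact test, adjusted p = 0.290). The 18 lower transcripts above the lowest value differed by a median of 12.4-fold. The abundant chaperones were among them. The authors' mean of an HSP70 (LOC_Os03g16860.1), which binds unfolded protein, was 63.9 in f5-i/j and 841 in f5-i/i, a 13.2-fold difference. For an HSP20 family protein (LOC_Os02g52150.2), of the small heat shock proteins, the authors' mean was 40.9 against 376. DnaJ proteins are co-chaperones of HSP70, and the authors' mean of DnaJ A2 (LOC_Os03g57340.1) was 175 against 653. Transcripts described as heat shock transcription factors were lower too. The authors' mean was 0.517 against 13.1 for LOC_Os03g46052.1, 0.337 against 7.91 for LOC_Os08g43334.1 and 0.107 against 16.3 for LOC_Os03g53340.3. Chaperonin GroES (LOC_Os06g09688.1) was at the lowest value in f5-i/j against the authors' mean of 29.1 in f5-i/i. The locus going both ways encodes the chaperone HtpG of the HSP90 family. Its most abundant transcript, LOC_Os08g39140.3, had the authors' mean of 229 against 886 and LOC_Os08g39140.2 had 0.820 against 265, whereas LOC_Os08g39140.1 was at 101 in f5-i/j and at the lowest value in f5-i/i.

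Among the largest ratios between f5-i/j and f5-i/i were those of ribosomal protein transcripts, which went both ways. Values here and in the other paragraphs are of single transcripts, and a locus may have other transcripts that were not listed. A lowest value thus need not mean that the locus was silent. Small subunit ribosomal protein S25e (LOC_Os08g44480.3) had the authors' mean of 374 in f5-i/i, SAe (LOC_Os03g08440.2) 80.7 and L13e (LOC_Os06g02510.5) 57.1, each at the lowest value in f5-i/j, while L15e (LOC_Os03g40180.2) was at 51.7 in f5-i/j and at the lowest value in f5-i/i. Sucrose synthase (LOC_Os03g28330.5), which splits sucrose, was at the authors' mean of 47.9 in f5-i/j and at the lowest value in both homozygotes. Among transcripts above the lowest value, glutathione peroxidase (LOC_Os04g46960.3) had the authors' mean of 0.0133 in f5-i/j and 30.3 in f5-i/i, ATP citrate lyase (LOC_Os01g19450.2) had 0.0767 against 25.6 and exportin-5 (LOC_Os11g31770.3) 0.127 against 17.9. Higher in f5-i/j were seryl-tRNA synthetase (LOC_Os01g37837.2), with the authors' mean of 7.88 against 0.0767, the 26S proteasome subunit 10 (LOC_Os09g33810.2), with 33.1 against 0.870, and ribosomal protein S15e (LOC_Os01g56780.3), with 19.9 against 0.573. The transcript with the largest ratio among these, LOC_Os12g36210.1, has no description and had the authors' mean of 38.0 against 0.367.

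Heat shock and chaperone loci were lower in f5-i/j than in f5-j/j as well. This comparison uses the same f5-i/j means as the one with f5-i/i. A deviation of the f5-i/j samples would lower the loci in both, so it is no independent replication. In the authors' deposited table, 15 of 16 loci were lower and 1 was higher, while 52.2% of the other loci were lower (two-sided Fisher's exact test, adjusted p = 0.0177; adjusted p = 0.0599 among transcripts with an absolute log2 ratio of at least 2). The group was over-represented, since 16 of the 19 loci found in any of the 3 authors' deposited tables were in this one (84.2%, against 41.9% of other loci; one-sided Fisher's exact test, adjusted p = 0.00326). The 15 lower transcripts above the lowest value differed by a median of 8.08-fold. The authors' mean of HSP70 (LOC_Os03g16860.1) was 63.9 in f5-i/j and 575 in f5-j/j, and that of HSP20 (LOC_Os02g52150.2) was 40.9 against 209. The heat shock transcription factors with the largest ratios had the authors' mean of 0.517 against 22.0 (LOC_Os03g46052.1), 1.37 against 34.6 (LOC_Os08g43334.2), 0.913 against 12.8 (LOC_Os09g35790.2) and 2.52 against 23.9 (LOC_Os04g48030.1). The single higher locus was a DnaJ A2 (LOC_Os04g46390.3), with the authors' mean of 10.95 in f5-i/j, the lowest value in f5-j/j and 93.8 in f5-i/i. In all, 10 loci of the group were lower in f5-i/j in both of the authors' deposited tables that include the heterozygote. Of the 16 transcripts of the group with a mean above the lowest value in all 3 genotypes, 13 had their lowest mean in f5-i/j. This count is no separate evidence, since 3 means exist only for transcripts in at least 2 of the authors' deposited tables, and 12 of the 16 were there because f5-i/j was listed lower than both homozygotes.

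**Figure D2:**
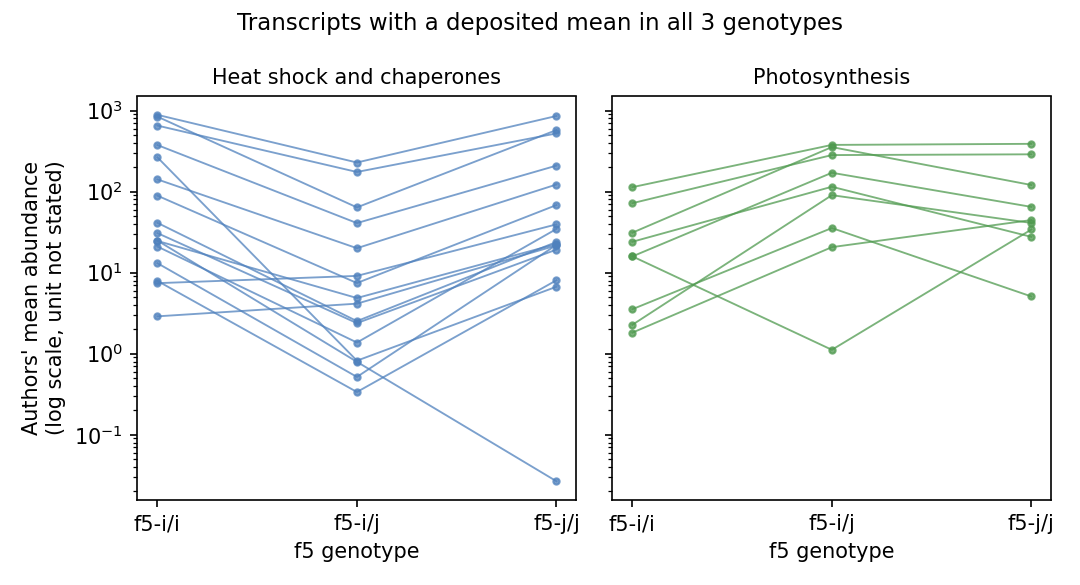
Authors' mean abundance (y axis, log scale, unit not stated) in the 3 genotypes (x axis) for transcripts above 0.01 in all 3, each line being 1 transcript: 16 of heat shock and chaperone loci (left) and 9 of photosynthesis loci (right). The lowest point is at f5-i/j for 13 of the 16 lines on the left and at f5-i/i for 8 of the 9 lines on the right, of which 12 and 6 were selected by being listed lower in that genotype in both of its tables.

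Of the other transcripts that differed between f5-i/j and f5-j/j, those described as cysteine endopeptidases with a KDEL tail were lower in the heterozygote. Proteases of that kind are active in cells that die during plant development. Whether the loci listed here encode the tail was not checked. The 3 loci had the authors' mean of 21.7 against 88.7 (LOC_Os04g55650.2), 2.69 against 17.6 (LOC_Os11g14900.4) and 7.32 against 33.6 (LOC_Os08g44270.1), but 3 loci in a single direction gave a two-sided Fisher's exact adjusted p of 0.729. Oxidation and detoxification loci leaned the other way, with 6 loci higher and 1 lower in the authors' deposited table (two-sided Fisher's exact test, adjusted p = 0.255). Peroxidases LOC_Os12g02080.2, LOC_Os03g22010.1 and LOC_Os05g04500.1 had the authors' mean of 37.3 against 7.84, 12.8 against 1.15 and 13.9 against 1.05. L-ascorbate peroxidase (LOC_Os07g49400.3), which removes hydrogen peroxide, was at the lowest value in f5-i/j, with the authors' mean of 41.9 in f5-j/j and 25.6 in f5-i/i. The MADS-box transcript LOC_Os02g49840.2, of a family of flower development regulators, had the authors' mean of 0.413 in f5-i/j, 39.5 in f5-i/i and 16.6 in f5-j/j. A myo-inositol transporter (LOC_Os10g39440.2) had 21.5 against 0.150 and a SETD2 histone methyltransferase (LOC_Os09g13740.2) 8.09 against 0.0467 by the authors' mean, both higher in f5-i/j. The largest fold above the lowest value was that of FAS-associated factor 2 (LOC_Os09g35710.2). The authors' mean was 0.0233 in f5-i/j, 12.4 in f5-j/j and 7.52 in f5-i/i. The first is near the lowest value, so the size of this fold is uncertain.

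The homozygotes were compared to see what the i and j alleles give without heterozygosity. Photosynthesis loci were lower in f5-i/i than in f5-j/j at all 6 loci in the authors' deposited table, which did not pass the correction (two-sided Fisher's exact test, p = 0.0341, adjusted p = 0.242). The authors' mean of light-harvesting complex II protein 1 (LOC_Os09g17740.1) was 113 in f5-i/i, 388 in f5-j/j and 377 in f5-i/j, and that of LOC_Os03g39610.2 was 71.9, 288 and 282 in the same order. Both loci described as LHY were lower in f5-i/i than in f5-j/j. The authors' mean was 1.45 against 75.5 (LOC_Os08g06110.2) and 14.1 against 97.6 (LOC_Os06g51260.1). In f5-i/j the latter was at 13.6. Heat shock and chaperone loci divided evenly between the homozygotes, with 2 higher, 2 lower and 1 going both ways in the authors' deposited table (two-sided Fisher's exact test, adjusted p = 1). Loci of chromatin, cell cycle and cytoskeleton were over-represented, with 12 of 13 loci in this authors' deposited table (92.3%, against 51.4% of other loci; one-sided Fisher's exact test, adjusted p = 0.0228). Of these, 9 were higher and 3 lower in f5-i/i (two-sided Fisher's exact test of direction, adjusted p = 0.242). The 4 with the largest ratios were a DNA polymerase lambda (LOC_Os06g13020.1), at the authors' mean of 9.87 in f5-i/i, a histone H1/5 (LOC_Os05g51850.1), at 7.59 in f5-j/j, a DNA polymerase kappa (LOC_Os03g42010.1), at 6.42 in f5-i/i, and the SCC1 subunit of the cohesin that holds sister chromatids together (LOC_Os04g41110.2), at 4.94 in f5-i/i, each at the lowest value in the other homozygote.

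Among other large differences between the homozygotes, the signal recognition particle receptor (LOC_Os08g37444.6), malate dehydrogenase (LOC_Os10g33800.3) and translation initiation factor 4G (LOC_Os01g42970.1) had the authors' mean of 105, 90.9 and 31.5 in f5-i/i and the lowest value in f5-j/j. Long-chain acyl-CoA synthetase (LOC_Os05g04170.4), on chromosome 5, and a tryptophan-pyruvate aminotransferase of auxin synthesis (LOC_Os01g55050.1) were at the authors' mean of 114 and 22.4 in f5-j/j and at the lowest value in f5-i/i. Above the lowest value, the heat shock transcription factor LOC_Os03g53340.4 had the authors' mean of 24.9 in f5-i/i, 0.0267 in f5-j/j and 0.793 in f5-i/j. Nucleophosmin (LOC_Os01g68160.2), a nucleolar protein, was at 14.2 against 0.0800 and a type-B response regulator of cytokinin signalling (LOC_Os01g74020.1) at 12.8 against 0.117 by the authors' mean.

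Few loci of the lists fixed for male reproduction could be found. Of 24 tapetum and pollen wall loci searched, 1 was in the authors' deposited tables. Of the 15 meiosis loci only 6 could be searched by identifier, the others being known here by identifiers of another kind, and none of the 6 was listed. The tapetum list member was C6 (LOC_Os11g37280.1), a lipid transfer protein of the tapetum, which nourishes developing pollen. It had the authors' mean of 0.413 in f5-j/j, 33.8 in f5-i/i and 34.1 in f5-i/j. Since the authors' deposited tables are filtered, an unlisted gene may be unchanged or not detected.

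The remaining groups gave no adjusted p of direction at or under 0.05. For f5-i/j against f5-i/i, f5-i/j against f5-j/j and f5-i/i against f5-j/j, in this order and as loci higher and lower in the authors' deposited tables without loci going both ways, they were as follows. Sugar and starch loci were 6 and 0, 1 and 1, and 2 and 4. The first of these splits had an adjusted p of 0.242 (two-sided Fisher's exact test), and it included granule-bound starch synthase (LOC_Os07g22930.4), with the authors' mean of 264 in f5-i/j, 82.8 in f5-i/i and 334 in f5-j/j, and beta-amylase (LOC_Os03g04770.1), with 21.7, 2.95 and 24.0. Chromatin, cell cycle and cytoskeleton loci were 0 and 5 in the first table and 3 and 1 in the second. MADS, MYB and bHLH transcription factors were 1 and 4, 0 and 2, and 2 and 3. Hormone loci were 4 and 1, 0 and 1, and 1 and 2, among them the jasmonate ZIM-domain repressor LOC_Os03g08330.1, with the authors' mean of 15.8 in f5-i/j, 1.5 in f5-i/i and 20.0 in f5-j/j. Photosynthesis loci were 4 and 0 in the second table. Loci matched for ubiquitin and F-box were 6 and 6, 6 and 8, and 6 and 7. The last 6 included naringenin 3-dioxygenase (LOC_Os03g32470.2), a flavonoid enzyme matched only by letters within its name. Transport loci were 3 and 0, 3 and 0, and 3 and 5. Oxidation and detoxification loci were 1 and 2 in the first table and 2 and 1 in the third. Mitochondrial respiration loci were 1 and 1, 1 and 1, and 0 and 1. Lipid and cuticle loci were 1 and 1 in the first table and 0 and 1 in the second. ER protein folding loci were 0 and 3 in the second table and 0 and 2 in the third, and cell wall and pollen tube loci were 2 and 0 in each of these. Protease and cell death loci were 0 and 1 in the first table. Phenylpropanoid and flavonoid loci were 0 and 1 in the first table and 1 and 0 in the second. WRKY, NAC, ERF and bZIP transcription factors were 1 and 0 in the first table and 0 and 1 in the third. Loci matched for defence and receptor kinases had the same counts, but the locus in the third table is a multidrug resistance protein of the MATE family (LOC_Os12g03200.2), a transporter. No listed locus had a description matched for transposons. Loci without a description could not be matched, so an absence of transposons is not shown.

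Across the 3 authors' deposited tables, 832 transcripts of 727 loci were listed, and 407 had a mean in all 3 genotypes because they were in at least 2 tables. The heterozygote lay above both homozygotes in 43 transcripts and below both in 96 transcripts listed in both of its authors' deposited tables. Leaving out transcripts with a lowest value gave 8 above and 49 below, the latter from 41 loci. For f5-i/i the counts in the authors' deposited tables were 76 above and 109 below, or 30 and 57 without transcripts at a lowest value. For f5-j/j they were 46 above and 49 below, or 12 and 12 without such transcripts. Tables that share a genotype share its chance deviations. The simulation of this used normal values of equal variance without a lowest value, unlike the deposited means. Its thresholds were set to reach the observed overlap and not the share of transcripts called, which is not known here. Its shares are thus not chance levels for these tables, and no conclusion is drawn from them. Among the 145 transcripts listed for f5-i/j against both homozygotes in the authors' deposited tables, 95.9% lay the same way, against 94.2% in simulated data without any effect, and this difference was not tested. The corresponding shares were 100% against a simulated 92.9% for the 185 transcripts in both authors' deposited tables with f5-i/i, and 94.1% against a simulated 98.7% for the 101 in both with f5-j/j. By mean alone, with no test and among transcripts selected by being listed at least 2 times, f5-i/j was above both homozygotes in 111, below both in 115 and between them in 181 of the 407 transcripts.

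Transcripts above both homozygotes and above the lowest value included the photosystem II oxygen-evolving enhancer protein 3 (LOC_Os07g36080.1), with the authors' mean of 35.5 in f5-i/j, 3.54 in f5-i/i and 5.08 in f5-j/j, and a polyneuridine-aldehyde esterase (LOC_Os01g70850.1), with 31.3, 3.37 and 4.40. Those at the lowest value in both homozygotes included an NADH dehydrogenase subunit (LOC_Os10g42840.2), at the authors' mean of 28.5 in f5-i/j, proteasome activator subunit 4 (LOC_Os08g38810.1), at 21.4, and 3-ketoacyl-CoA synthase (LOC_Os03g08360.3), which elongates fatty acids, at 9.20. Below both were a WNK protein kinase (LOC_Os01g64560.1), with the authors' mean of 0.0700 in f5-i/j, 5.61 in f5-i/i and 8.34 in f5-j/j, and an NADH dehydrogenase subunit (LOC_Os06g50000.2), at the lowest value in f5-i/j with 51.1 and 41.8 in the homozygotes.

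The distribution over chromosomes was asked for because the plants segregate at f5, which has been mapped to chromosome 5. That chromosome held 36 of 427 loci (8.43%) for f5-i/j against f5-i/i, 37 of 313 (11.8%) for f5-i/j against f5-j/j and 44 of 379 (11.6%) for f5-i/i against f5-j/j in the authors' deposited tables. Set against the listed loci of the other comparisons, these shares gave adjusted p-values of 0.282, 0.739 and 0.739 (two-sided Fisher's exact test). An excess on chromosome 5 common to all 3 comparisons could not show in this test, since all loci it used were listed in them. None of the 36 tests over 12 chromosomes passed the correction, and 3 had an unadjusted p of at most 0.05. Weighted by locus number, chosen after seeing the data, none passed either (lowest adjusted p = 0.136, exact binomial test) and 8 had an unadjusted p of at most 0.05. For chromosome 5, whose share by locus number is 8.27%, this exact binomial test gave p = 0.861 for f5-i/j against f5-i/i, p = 0.0303 (adjusted 0.156) for f5-i/j against f5-j/j and p = 0.0246 (adjusted 0.153) for f5-i/i against f5-j/j, the share being higher in each. The densest stretch of chromosome 5, by locus numbers from 38000 to 39999, held 6 loci for f5-i/j against f5-j/j in the authors' deposited table. They included ribosomal protein S26e (LOC_Os05g39960.3), at the lowest value in f5-i/j with the authors' mean of 40.4 in f5-j/j, and the ubiquitin ligases TRIP12 (LOC_Os05g38830.1), with 11.6 in f5-i/j and the lowest value in f5-j/j, and HERC4 (LOC_Os05g38270.2), with 8.55 against 37.9.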

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

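Counting loci in place of transcripts, counting repeated rows once, weighting by locus number, giving mixed loci the direction of their summed means, and the group tests on transcripts or without the lowest value were chosen after the data were seen. Apart from a setting that removed no transcript (a higher mean of at least 1), 89 recomputed values stayed on their side of the threshold or within 1.5 times, 16 counts moved further, 1 call was lost and 1 direction turned. The lost call was that of a group: with an absolute log2 ratio of at least 2, the adjusted p of heat shock and chaperone loci in f5-i/j against f5-j/j was 0.0599, and over all settings it ranged from 0.000891 to 0.0599. A probability of at least 0.9 left 112, 99 and 108 transcripts for f5-i/j against f5-i/i, f5-i/j against f5-j/j and f5-i/i against f5-j/j, fewer by construction since the threshold is stricter. Leaving out the lowest value left 252, 147 and 207, again by construction. Under that setting f5-i/j lay above both others in 8 and below in 49 transcripts, f5-i/i above in 30 and below in 57, and f5-j/j above in 12 and below in 12. By position alone f5-i/j was then above both homozygotes in 38, below in 64 and between in 62. With the lowest values kept in, a margin of 1.5-fold left f5-i/j above both in 67 transcripts, against 111 without the margin. Chromosome 5 held a smaller share for f5-i/j against f5-i/i than for the other comparisons, but a slightly larger share than its locus numbers would give (8.43% against 8.27%, exact binomial test, adjusted p = 0.968); the cause was not tested.

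No paired analysis was possible because the tables hold genotype means and no values of single samples. For the same reason fits with a replicate block, another pseudocount and left-out replicates were not run, and how far any call rests on 1 sample is open. Windows of chromosome length, at any size, and the annotated genes as background were not run, for want of positions and identifiers that match. Depth is unknown, so it cannot be said which of the lowest values are limits of detection.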

Other observations

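Most tests in this part were run on groups or explanations chosen after the tables were seen. The exceptions are those of reads divided between transcript models, of the f5 interval and of the direction of photosynthesis loci. Lysine-specific demethylases, which remove methyl groups from histones, were lower in f5-i/j than in f5-i/i at all 3 listed loci. They were lower in f5-i/j than in f5-j/j at 1 locus and higher in f5-i/i than in f5-j/j at 2 loci. Demethylase 8 (LOC_Os09g31380.1) had the authors' mean of 30.6 in f5-i/i, 4.31 in f5-i/j and 4.59 in f5-j/j, and demethylase 3 (LOC_Os01g35050.4) had 21.8, 3.39 and 31.4. The two-sided Fisher's exact test of the first count gave p = 0.0951 and an adjusted p of 0.688 over 27 tests. Ribosomal protein loci were 4 higher and 9 lower in f5-i/j than in f5-i/i in the authors' deposited table (adjusted p = 0.688). Enolase (LOC_Os10g08550.5), of glycolysis, had the authors' mean of 270.2 in f5-i/i, 54.6 in f5-i/j and 299.6 in f5-j/j. Other glycolysis loci went both ways, such as fructose-bisphosphate aldolase (LOC_Os11g07020.4), with the authors' mean of 51.4 in f5-i/j and 15.3 in f5-i/i. In the authors' deposited tables, glycolysis loci were 2 higher and 3 lower in f5-i/j than in f5-i/i, 1 and 3 against f5-j/j, and 4 and 2 in f5-i/i against f5-j/j (two-sided Fisher's exact test, adjusted p = 0.944, 0.943 and 0.821). Stress-induced phosphoprotein 1 (LOC_Os06g06490.1), a co-chaperone outside the fixed group, had the authors' mean of 97.6 in f5-i/i, 12.3 in f5-i/j and 89.6 in f5-j/j.

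Clock and flowering-time transcripts other than LHY were listed in both directions. FKF1 (LOC_Os11g34460), a light-sensing F-box protein, had the authors' mean of 18.3 in f5-i/i and 2.69 in f5-j/j for transcript 1, and of 17.3 in f5-i/i and 2.38 in f5-i/j for transcript 2. CONSTANS zinc finger proteins had the authors' mean of 89.0 in f5-i/i and 285 in f5-j/j (LOC_Os09g35880.1), of 7.56 in f5-i/i and 32.1 in f5-i/j (LOC_Os06g44450.1), and of 4.34 in f5-i/i with the lowest value in f5-i/j (LOC_Os06g19444.2). Of the DOF5.5 proteins, LOC_Os01g15900.1 had the authors' mean of 1.25 in f5-i/i, 14.1 in f5-i/j and 16.4 in f5-j/j, and LOC_Os07g48570.1 had 6.62 in f5-i/i and 29.99 in f5-j/j. LOC_Os02g45200.2 went the other way, with the authors' mean of 5.30 in f5-i/i and the lowest value in both others.

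Heat shock and chaperone loci were lower in the heterozygote against both homozygotes, in comparisons that share the f5-i/j means. A scaling of all f5-i/j values would lower all transcripts alike. It is argued against as the whole cause by the comparison with f5-i/i alone. There 133 of the 215 other transcripts above the lowest value were higher in f5-i/j than in f5-i/i. The other 38.1% were lower (two-sided exact binomial test against equal shares, p = 0.000616). That test takes transcripts as independent, so its p-value may be too small. Photosynthesis transcripts, which moved together, made up 22 of the 133 higher ones and 1 of the lower ones. Against f5-j/j the others leaned the way a scaling would, 73 of 123 (59.3%) being lower (two-sided exact binomial test, p = 0.0469). A scaling as part of that difference thus stays open. Comparing these with the group itself (two-sided Fisher's exact test, larger p = 0.00107) restates the group's own test and adds no evidence. Reads divided differently between transcript models cannot be told apart from a lower level of the locus: the summed means were more than 1.5-fold lower in 100% of the 15 loci, but 10 of these had 1 listed transcript, for which the listing sets the outcome, and the other 5 lack their unlisted transcripts. A warmer or cooler hour of collection may have moved all heat shock transcripts together, and it cannot be told apart from genotype, since 0 of the 9 samples have a collection time or temperature in their labels. An effect of f5 heterozygosity on chaperone transcripts stays open as the biological hypothesis and was not tested.

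Photosynthesis loci were lower in f5-i/i than in f5-i/j, while against f5-j/j only 6 of the 22 loci were listed, all lower (two-sided Fisher's exact test, adjusted p = 0.242), and f5-i/j had the highest mean in 5 of 9 transcripts with 3 means above the lowest value, so that a high heterozygote is part of the pattern. Collection at different times of day is a candidate explanation. Of the 3 loci described as LHY or FKF1 and listed for the homozygotes, those of LHY were lower and that of FKF1 higher in f5-i/i. A different hour could leave them so, but they were picked after their directions were seen and no hour was predicted. Their count is thus no separate evidence. LOC_Os06g51260.1, described as LHY, was as low in f5-i/j (13.6) as in f5-i/i (14.1). A shared hour of f5-i/j and f5-j/j would not give this. CONSTANS and DOF5.5 loci went both ways, but those above the lowest value were all lower in f5-i/i. LOC_Os06g19444.2 and LOC_Os02g45200.2, which went the other way, were at the lowest value in f5-i/j. A smaller share of green tissue in the f5-i/i spikelets cannot be told apart from a different hour of collection. Of 22 transcripts, 17 (77.3%) lay within 1.5-fold of the median fold. But 1.5-fold below the median is 2.83-fold, under the smallest fold listed for the group. The listing thus fixes part of this share, and the share decides nothing. Reads divided between transcript models stay open too, as the summed means were more than 1.5-fold lower in 100% of 21 loci, of which 16 had 1 listed transcript. A difference between the i and j alleles stays open, untested.

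Transcripts at the lowest value in 1 of the 2 genotypes made up 51.6% of all entries in the authors' deposited tables. Sequence or presence differences in the f5 interval alone are argued against: 45 of 411 such transcripts lay on chromosome 5 (10.9%), against 9.50% of the others (two-sided Fisher's exact test, p = 0.495), so most lay elsewhere. An allele absent from a homozygote would still be present in f5-i/j. Of the 243 such transcripts with 3 means, 48 (19.8%) were at the lowest value in f5-i/j alone with means above 1 in both homozygotes. An absent allele would not give these. It could give the 54 at the lowest value in f5-i/i alone and the 40 in f5-j/j alone. The lowest value was reached in 2 genotypes by 98. The division of reads between models of a locus is consistent with the pattern, since 71.5% of the transcripts at the lowest value were numbered 2 or above within their locus, against 52.3% of the other listed transcripts (two-sided Fisher's exact test, p = 1.06e-08). The test took transcripts as independent, although some carry the same values as another transcript of their locus, so its p-value may be too small. The division of reads may account for part of these calls, and a real change of splicing would leave the same trace.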
